A study of Mus musculus with 2 samples.

How the data were processed

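Total RNA from the small intestine of IL-9 transgenic mice and of wild-type mice, both on the BALB/c background and 6 to 8 weeks old, was labelled with biotin and hybridised to Affymetrix mouse expression arrays. IL-9 is a cytokine of the type 2 immune response that promotes mast cell growth. Each of the 2 arrays carried RNA from 1 pool of 3 mice, and 10 µg of total RNA entered the labelling, per the labels' protocols. Samples were grouped by the source given in their labels. The group sizes are therefore 1 array against 1 array, the spread between mice cannot be estimated, and no p-value is given for any gene. "Transgenic pool" and "wild-type pool" name the arrays as the labels do.

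The deposited values are intensities of probe sets (groups of short probes that target one transcript) on a linear scale, from 5.60 to 24147 on the transgenic array and from 5.75 to 25799 on the wild-type array. RMA is named in the submitters' processing notes, without a version. RMA corrects the background, equalises the distributions of the arrays and summarises the probes of a set on the log2 scale, so the deposited intensities had been returned to a linear scale. The median intensity was 78.7 on the transgenic array and 78.3 on the wild-type array, which leaves no overall shift between them. Because RMA forces the distributions of the arrays together, a change of the same size in most genes could not be seen in these values. The deposited intensities come without detection calls, so no gene is called absent, and background signal shrinks the fold changes of dim genes. The genome build and the chip annotation used by the authors are not given in the sources used here.

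Gene names were taken from a platform annotation table. Of 45101 probe sets, 34958 carried 1 gene symbol, 932 carried several and 9211 had no symbol in that table. Entrez identifiers of 34754 probe sets were found in the RefSeq gene table of mouse assembly GRCm38.p6, and 0 symbols needed an update. Probe sets with several symbols or none name no gene here. Genes without a probe set of their own name in that table were not analysed here. Each of the 18194 genes was represented by its probe set with the highest mean over both arrays. Values were taken as log2(intensity + 1), and differences are the transgenic pool minus the wild-type pool, so folds are on this scale and understate the change of dim genes. A gene passed the expression filter when the higher of its 2 log2 values reached the median of all values, 6.31, which is an intensity of 78.5. This left 11862 genes.

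Genes were counted as higher or lower when they differed by 2-fold, a difference of 1 on the log2 scale. The only repeat measurement in the design is that some genes have several probe sets on the same arrays. Over 4965 genes with several probe sets past the filter, the SD of the log2 difference between probe sets of one gene was 0.23. This figure describes technical spread within the arrays and says nothing of the spread between mice.

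A total of 38 gene lists for cell types and pathways was fixed before the data were examined, as were the expression filter, the size of change, the random lists and the rule for naming genes. For each list with at least 3 members past the filter, the median difference was set against 10000 random lists of the same size, matched on mean expression in 20 bins. A list is described as apart from random lists when its percentile lay above 97.5 or below 2.5. Of 35 lists with a percentile, 1.75 would lie there by chance if the genes of each list varied independently. Genes of the same cell type can move together when pools differ in tissue make-up, and some lists share members. More lists than 1.75 can therefore lie there through sampling of the tissue alone, and the figure is no test of the number found. The percentiles describe these 2 arrays only. The genes named are Il9, the 15 highest and the 15 lowest genes past the filter (leaving out antigen receptor segments and names with no assigned gene), and from each list up to 4 members past 2-fold, or the 2 with the largest difference where fewer passed. All members of the mast cell and tight junction lists could be named, since mast cells and intestinal permeability are the subject of the series title. All other genes named, among them further members of the lists and the genes of the closing observations, were chosen after their values were seen.

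The procedure was tested on simulated data made from the wild-type array, with noise of SD 0.20 on the log2 scale and 11833 genes past the filter. It recovered 100 of 100 genes raised by 1.5 on the log2 scale, 50 of 50 raised by 2 and 49 of 50 lowered by 2, and called 0 of 11633 unchanged genes. The noise is well under the 2-fold threshold and leaves out the spread between mice, so this checks the computation only and gives no rate of false calls for these pools. The alternatives were the mean over a gene's probe sets, leaving out probe sets that can match other transcripts (IDs ending in _x_at or _s_at), no filter or a filter at the 75th percentile, median centring, removal of a loess trend, quantile normalization, a pseudocount of 16, thresholds of 1.5-fold and 3-fold, and 5 expression bins. Leaving out list members that another list also holds was added after the data had been seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.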

Results

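Gene expression in the small intestine was compared between mice that carry an IL-9 transgene and wild-type mice, with 1 array for each pool of 3 animals, in a study of mast cells, intestinal permeability and reactions to oral antigen. There were no replicate arrays, so every value below is a single measurement of a pool and no difference has a replicate check. The log2 values of the 2 arrays correlated with Pearson r = 0.994 across all probe sets, which are not independent replicates. Of 11862 genes past the expression filter, 95% differed by between -0.49 and 0.50 on the log2 scale. In the probe sets for actin at the 3′ and 5′ ends of the transcript, a sign of RNA integrity, the 3′ to 5′ ratio was 1.33 in the transgenic pool and 1.61 in the wild-type pool. For Gapdh the ratios were 1.08 and 1.22, while the log2 ratios were higher in the transgenic pool for pyruvate carboxylase (1.95 against 1.84) and the transferrin receptor (2.20 against 1.84).

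Il9 itself was not higher in the transgenic pool. Its only probe set read 62.2 in the transgenic pool and 71.6 in the wild-type pool, a log2 difference of -0.20, and both values lay below the expression filter. The labels do not say which part of the gene the transgene carries or where it is expressed, so this probe set does not check the labels, and all directions below rest on the labels alone.

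Genes of the epithelium and of mast cells were among those with the largest differences between the pools. A total of 72 genes were higher by 2-fold and 24 were lower, while 11766 differed by less. The largest difference was in Gsdmc2, a gasdermin of the pore-forming protein family, which read 4989 in the transgenic pool and 158 in the wild-type pool, 31.4-fold higher. St3gal4, a sialyltransferase, was 14.3-fold higher (911 against 62.9), Pla2g4c, a cytosolic phospholipase A2, was higher by 3.81 on the log2 scale (5293 against 377), and Retnlb, a goblet cell peptide of type 2 immunity, was 12.5-fold higher (567 against 44.6). Duoxa2, the maturation factor of a hydrogen peroxide-producing oxidase, was 6.68-fold higher, Pmm1, a phosphomannomutase, 5.48-fold, and Me1, the cytosolic malic enzyme, 5.27-fold. Of 26 genes past 2-fold that had several probe sets past the filter, 25 had all of them in one direction, the exception being Ang, and 14 had all of them past 2-fold. Probe sets of Gsdmc2 can share sequence with other gasdermin C genes, so its value may hold signal from its paralogs. At 3-fold the counts were 31 higher and 3 lower.

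**Figure D1:**
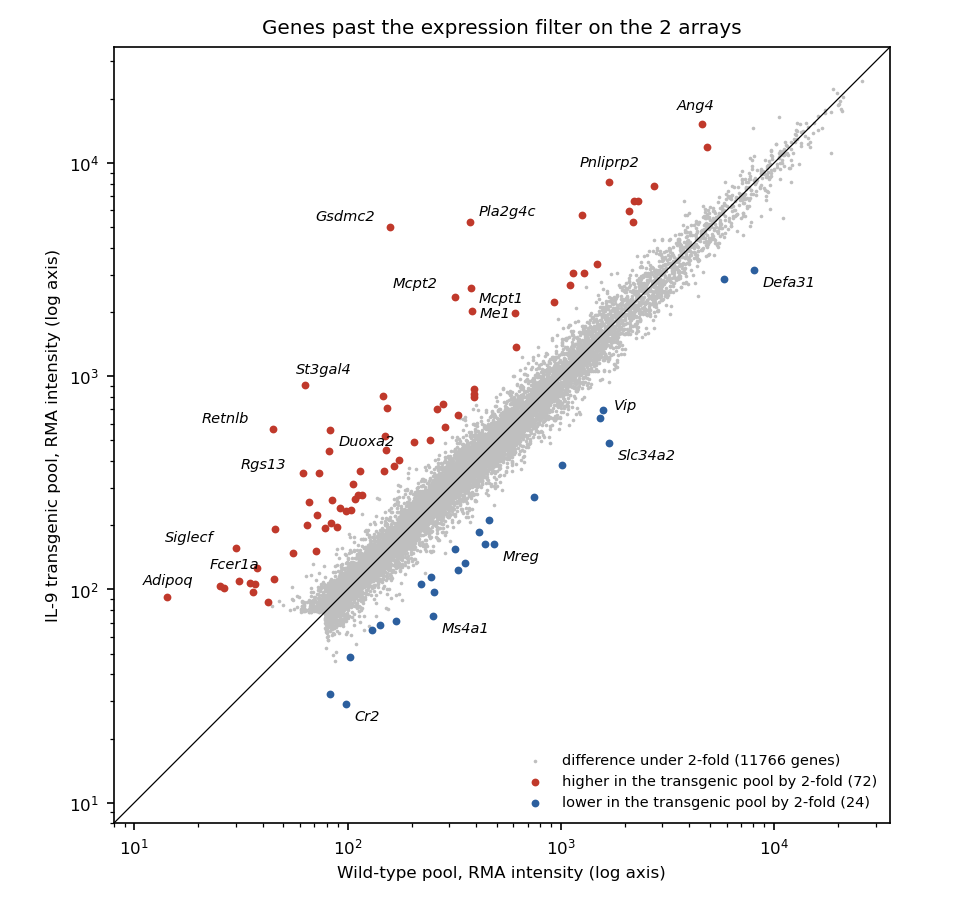
RMA intensity of each gene in the wild-type pool (horizontal, log axis) and the IL-9 transgenic pool (vertical, log axis), 1 point per gene past the expression filter, with the line of equal values. The 72 genes higher by 2-fold (red) include Gsdmc2, Pla2g4c, St3gal4, Mcpt1 and Mcpt2, and the 24 lower genes (blue) include Slc34a2, Ms4a1 and Cr2.

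Mast cell genes were higher in the transgenic pool. Of 11 members of the mast cell list past the filter, 4 were higher by 2-fold, 0 were lower by 2-fold and 10 lay above 0. The median log2 difference of 0.71 exceeded all 10000 random lists. Fcer1a and Cpa3 passed the filter through the transgenic pool alone, and without a filter the median was 0.52. Mcpt2 and Mcpt1, the chymases of mucosal mast cells, were 7.39-fold (2364 against 319) and 6.82-fold higher (2586 against 378). Fcer1a, the alpha chain of the high-affinity IgE receptor, was 3.45-fold higher (109 against 31.0) and Cpa3, mast cell carboxypeptidase, 2.46-fold higher (194 against 78.3). Tpsg1, a tryptase, and Kit, the stem cell factor receptor, differed by 0.75 and 0.71 on the log2 scale, Rab27b by 0.52, Srgn by 0.50, Gata2 by 0.24 and Cma1, the chymase of connective tissue mast cells, by 0.18. Hdc, the histamine-forming decarboxylase, differed by -0.19. Mcpt4, a further chymase, read 78.3 against 47.7, and the tryptases Tpsb2 and Tpsab1 read 60.8 against 48.6 and 21.8 against 20.2, all below the filter. Mcpt1 and Mcpt2 are close paralogs, and cross-hybridisation between their probe sets cannot be excluded.

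Tuft cell genes were higher in the transgenic pool. Tuft cells are chemosensory cells of the epithelium. All 10 members past the filter lay above 0, 5 of them by 2-fold, and the median log2 difference of 1.22 exceeded all 10000 random lists. The median was 0.64 without a filter, 0.86 with the mean over probe sets and 1.95 with the filter at the 75th percentile, each above all random lists. Of the 10 members, Rgs13, Avil, Dclk1, Sh2d6 and Il17rb passed the main filter through the transgenic pool alone. Rgs13, a regulator of G protein signalling, was 5.63-fold higher (352 against 61.7), Avil, the actin regulator advillin, 4.73-fold (353 against 73.9), Dclk1, a kinase used as a tuft cell marker, 3.86-fold (257 against 65.9) and Alox5ap, which serves leukotriene synthesis, 3.49-fold (524 against 149). The 5 probe sets of Dclk1 past the filter all lay above 0, the lowest at 0.68, and the mean over all its probe sets was 0.81. Trpm5, the cation channel of taste-like cells, differed by 0.83, and Pou2f3, the transcription factor of the lineage, by 0.17. The SD of differences between probe sets of one gene is 0.23.

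In the goblet cell list, 2 of 15 members were higher by 2-fold, 0 were lower by 2-fold and 11 lay above 0, and the median of 0.52 exceeded all 10000 random lists. These 2 were Retnlb and Ang4, an antimicrobial ribonuclease that is also on the Paneth cell list (15190 against 4590, 3.31-fold). Clca1, a secreted goblet cell protein, differed by 0.87, and Atoh1 and Spdef, transcription factors of the secretory lineage, by 0.85 and 0.84. The main mucin gene Muc2 differed by 0.09 and Tff3, a trefoil peptide, by -0.0043. In the Paneth cell list, 4 of 10 members were higher by 2-fold, and the median of 0.36 exceeded all 10000 random lists. Only 11 of the 25 genes listed were named on the array, and no defensin is among the 10 behind this median. The 4 were Ang4, Mptx1, a mucosal pentraxin (2.89-fold), Clps, colipase (2.84-fold), and Ang (2.43-fold), while Lyz1, lysozyme, differed by -0.25. Ang lay at -0.59 without probe sets that can match other transcripts, so its direction is uncertain. Without members of other lists the Paneth cell median was 0.27, at percentile 99.5, and with the filter at the 75th percentile it was 0.84. Defa31, a Paneth cell defensin outside the list, was 2.57-fold lower (3142 against 8089), measured by a probe set that can match related defensins. Defa39 differed by -0.75, and a probe set shared by Defa30 and Defa24 by -0.06.

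**Figure D2:**
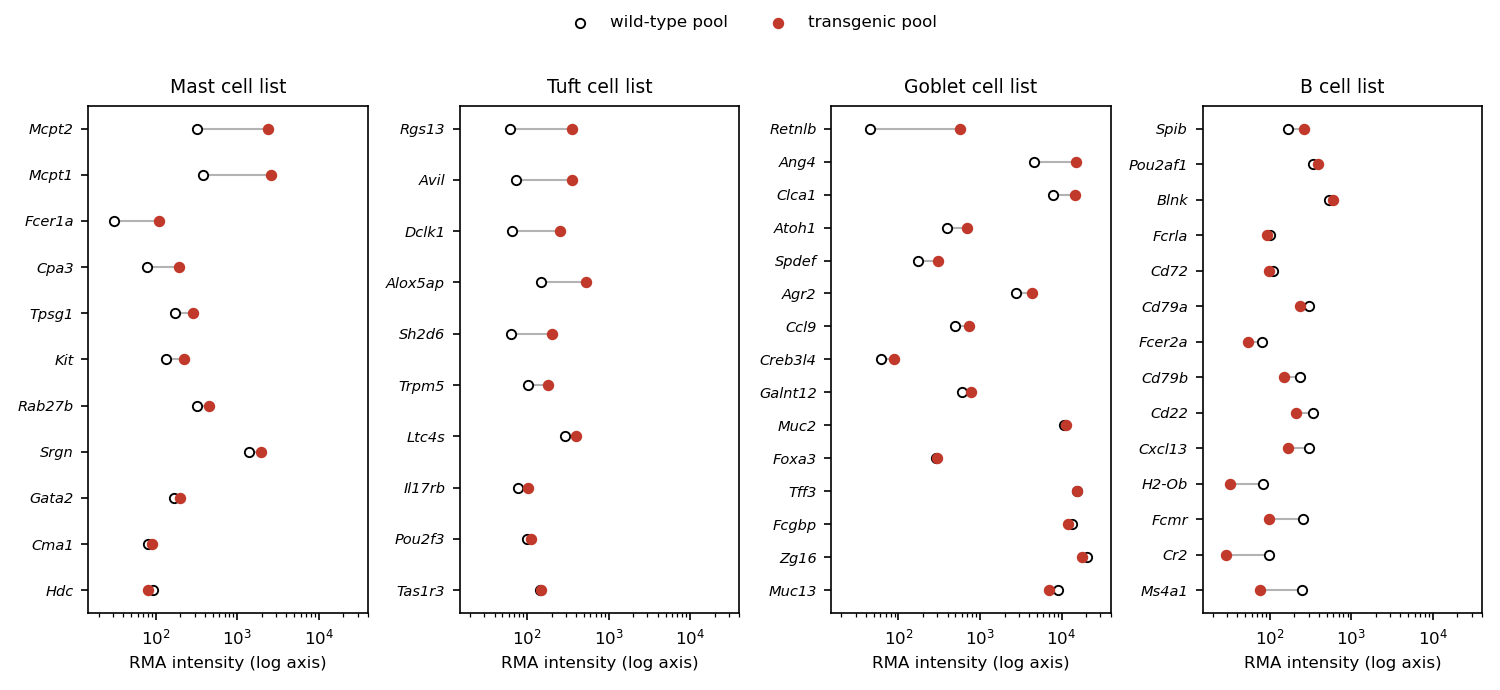
RMA intensity (horizontal, log axis) of the members past the expression filter of 4 gene lists, in the wild-type pool (open circles) and the IL-9 transgenic pool (filled circles), 1 value per pool. Mcpt2 and Mcpt1 lead the mast cell list, Rgs13 and Avil the tuft cell list and Retnlb the goblet cell list, while Ms4a1 and Cr2 were lower in the transgenic pool.

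Some lipid mediator and type 2 immune genes were higher in the transgenic pool. In the list of eicosanoid, histamine and platelet-activating factor genes, 3 of 17 members were higher by 2-fold and the median of 0.13 was within random lists, at percentile 96.9. These were Pla2g4c, Alox5ap and Alox5, the 5-lipoxygenase (2.42-fold). The median depended on the setting: it was 0.44 with the filter at the 75th percentile, above all 10000 random lists, 0.04 without a filter and -0.02 with the mean over probe sets, both within random lists. Ccl11, the eosinophil attractant eotaxin, was 2.92-fold higher (313 against 106), and Il33, an epithelial and stromal alarmin, differed by 0.59. The other members of the type 2 list were under 2-fold, and its median of 0.15 lay within random lists, at percentile 93.4. Il4, Il5, Il25 and Tslp read below the filter in both pools, and Il13 differed by 0.12. In the eosinophil list, 2 of 7 members named on the array passed the filter. Siglecf, a lectin on this list, was 5.07-fold higher (156 against 30.0) and Alox15 differed by 0.32. The granule genes Epx and Prg2 lay below the filter in both pools, with differences of 0.04 and -0.21. These values do not show a difference in eosinophils. In the list of alternatively activated macrophages, 4 of 9 members named on the array passed the filter. Their median was 0.52, at percentile 99.9, and 1 of the 4 was past 2-fold. This was Retnla, a resistin-like cytokine, at 3.12-fold. Ccl8 differed by 0.62, Clec10a by 0.43 and Mrc1 by -0.05, and Clec10a passed the filter through the transgenic pool alone. No member of the basophil list passed the filter.

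B cell genes were lower in the transgenic pool. Of 14 members past the filter, 4 were lower by 2-fold, 0 were higher by 2-fold and 11 lay below 0, and the median of -0.59 was below all 10000 random lists. With the filter at the 75th percentile it was -0.36, still apart from random lists. Of the 4 past 2-fold, Ms4a1, Cr2 and H2-Ob passed the main filter through the wild-type pool alone. Ms4a1, the B cell antigen CD20, was 3.33-fold lower (74.9 against 251), Cr2, the complement receptor CD21, 3.31-fold lower (29.0 against 98.3), Fcmr, the IgM receptor, was 2.59-fold lower and H2-Ob, a B cell modulator of antigen loading, differed by -1.32. Cxcl13, the chemokine of B cell follicles, differed by -0.84, and Madcam1, the addressin of mucosal vessels, by -0.52. In the plasma cell and immunoglobulin list 0 of 12 members passed 2-fold, 10 lay above 0, and the median was 0.19, at percentile 99.5. Mzb1 and Fkbp11, genes of antibody-secreting cells, differed by 0.60 and 0.72 (Fkbp11 by 0.21 as the mean of its probe sets), and Jchain, the joining chain of secreted antibodies, by 0.13. Among antigen receptor segment genes, 4 were higher by 2-fold and 1 was lower. For T cells and cytotoxic lymphocytes the median was 0.04, for MHC class II 0.01, for macrophages and dendritic cells 0.12 and for neutrophils 0.17, all within random lists, with 0 members past 2-fold. The largest differences there were 0.40 in Cd8a, 0.43 in Cx3cr1, -0.44 in H2-DMb2 and 0.51 in Mmp9, with Cd8a at 0.11 and Cx3cr1 at 0.24 as the mean of their probe sets.

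Tight junction and adhesion genes showed no difference of 2-fold. Of 26 members past the filter, 13 lay above 0 and 13 below, the median was -0.0023, at percentile 46.6, and the values ran from -0.48 in Cldn12 to 0.35 in Cldn4. Cldn15 and Cldn2, which form paracellular cation pores, differed by 0.29 and -0.04, Cldn3 by 0.03, Cldn7 by -0.16 and Cldn23 by 0.15. Ocln, occludin, differed by 0.20, Tjp1, the scaffold ZO-1, by 0.25, F11r, a junctional adhesion molecule, by -0.16, Cdh1, E-cadherin, by -0.23, and Mylk, the myosin light chain kinase, by -0.21. These values compare with the SD of 0.23 between probe sets of one gene. The other probe set of Ocln past the filter lay at -0.25, that of Cldn2 at 0.44 and that of F11r at 0.09. Those of Mylk and Ctnnb1 reached 0.03 and 0.55, so no direction is given for Ocln, Cldn2, F11r, Mylk and Ctnnb1. The probe sets of Cldn3 past the filter all lay above 0, from 0.03 to 0.45, but the lowest fell to -0.0049 under quantile normalization. The range above holds for 1 probe set per gene only. The levels of Cldn1 and Cldn8 were below the filter.

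Of 23 brush border and absorption genes 0 passed 2-fold, 15 lay below 0, and the median was -0.09, at percentile 7.45. Apoa1, Fabp1 and Alpi, an apolipoprotein, a fatty acid-binding protein and the intestinal alkaline phosphatase, differed by -0.10, 0.12 and 0.03, and the largest differences in the list were 0.41 in Slc2a5, the fructose transporter, and -0.37 in Npc1l1, the cholesterol transporter. Enteroendocrine genes had a median of 0.02, with 0.61 in Tph1, the serotonin-forming hydroxylase, and 0.45 in Gcg, proglucagon. Stem cell genes had a median of -0.04. Cell cycle genes had a median of 0.13, at percentile 98.8, with 0 of 23 past 2-fold and the largest values in Bub1 (0.61, or 0.26 as the mean of its probe sets) and Ccnb2 (0.52). The proximal and distal small intestine lists had medians of 0.03 and -0.10. In these, Cubn, the receptor for the vitamin B12 carrier, was 2.05-fold lower, Onecut2 differed by -0.57, Slc51b by 0.49 and Adh6a by 0.41.

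In the list of enterocyte antimicrobial genes, 2 of 10 members were higher by 2-fold, Duoxa2 and Reg4, a lectin of the regenerating family (2.99-fold), while 8 lay below 0. The median was -0.19, at percentile 1.34, and the mean was 0.12, so the direction of this list depends on the summary. Without a filter and with the filter at the 75th percentile the list lay within random lists. Over the alternatives its median rose to at most -0.07. The antibacterial lectin Reg3b read 5540 against 11069, a difference of -0.998, under 2-fold, and Reg3g differed by -0.89.

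Slc34a2, the intestinal phosphate transporter, was the lowest of the named genes, at 3.48-fold lower (485 against 1689). Mreg, melanoregulin, was 2.98-fold lower, Mid1, a microtubule-associated ubiquitin ligase, 2.75-fold, Trim30d 2.66-fold, Tmigd1 2.66-fold, Rab30 2.64-fold, Sgk1, a kinase that regulates ion transport, 2.40-fold, Lect2 2.35-fold and Vip, the neuropeptide of enteric neurons, 2.29-fold. The mean over all probe sets of Mid1 was -0.55. In the fatty acid oxidation list, 2 of 14 members were lower by 2-fold, Pdk4, the pyruvate dehydrogenase kinase (2.68-fold), and Angptl4, an inhibitor of lipoprotein lipase (2.05-fold). The median of that list, -0.08, was within random lists. Angptl4 lay at -0.04 without probe sets that can match other transcripts, so its difference rests on such a probe set.

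Some genes on the adipose, pancreas and liver lists were higher in the transgenic pool. Adipoq, the adipocyte hormone adiponectin, was 6.07-fold higher (91.9 against 14.3) and Car3, a carbonic anhydrase abundant in fat, 3.09-fold. The adipose list had a median of 0.44 over 7 members, at percentile 99.99. It was 0.23 without a filter and 0.25 with the mean over probe sets, still apart from random lists, and Adipoq passed the filter through the transgenic pool alone. In the exocrine pancreas list, 3 of 10 members were higher by 2-fold, and the median of 0.08 was within random lists, but with the filter at the 75th percentile it was 0.81, at percentile 99.99. These were the lipase-related genes Pnliprp1 (5.42-fold) and Pnliprp2 (4.86-fold), with Clps. In the liver list, 2 of only 3 members past the filter were higher by 2-fold, Cyp2e1 (2.83-fold) and Apoh (2.35-fold), with the mean over all probe sets of Apoh at 0.62. The liver median of 1.23 was 0.071 without a filter. The smooth muscle list had a median of 0.16, at percentile 98.8, with 0 of 15 past 2-fold, 0.34 in Des (0.18 as the mean of its probe sets) and -0.46 in Pln. In the stroma list Fn1, fibronectin, was 2.40-fold higher and Col6a1 differed by 0.70, around a median of 0.04. The enteric neuron and glia list had a median of -0.04, with Snap25 at -0.51, or of -0.39 as the mean over probe sets, at percentile 0.01, and the endothelial list one of -0.06, with Tek at -0.52.

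The remaining lists had 0 members past 2-fold. Cholesterol synthesis genes had a median of 0.14, at percentile 98.3, with 0.77 in Fdps and 0.60 in Sqle. Interferon response genes had a median of 0.0032, with -0.66 in Ifit1 and 0.56 in Irgm1. The xenobiotic list had a median of -0.05, with 0.87 in Cyp2c29 and 0.69 in Gstm3. Genes that respond to tissue handling had a median of -0.08, with -0.49 in Jun and 0.39 in Btg2, and the heat shock and endoplasmic reticulum stress list one of 0.04, with -0.64 in Hsph1 and 0.60 in Chac1. The circadian clock list, whose members peak at different times of day so that its median does not check the time of sampling, had a median of 0.04, with -0.85 in Npas2 and 0.62 in Per3. As the mean of their probe sets, Npas2 lay at -0.48, Per3 at 0.21, Fdps at 0.47, Hsph1 at -0.36 and Btg2 at 0.12. Both pools expressed Xist at a similar level (2383 and 2605), and the Y-linked genes Eif2s3y and Uty read at most 23.8. Of 35 lists with a percentile, 11 stood apart on the high side and 2 on the low side. With the filter at the 75th percentile the antimicrobial, cell cycle, plasma cell and cholesterol synthesis lists lay within random lists, as did the smooth muscle list under quantile normalization and the liver list without a filter. The macrophage and dendritic cell list stood apart on the high side without a filter, and the brush border list on the low side with the mean over probe sets. Median and mean differed in sign for the antimicrobial list and, with both near 0, for the proximal intestine, interferon, circadian, heat shock and xenobiotic lists.

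**Figure D3:**
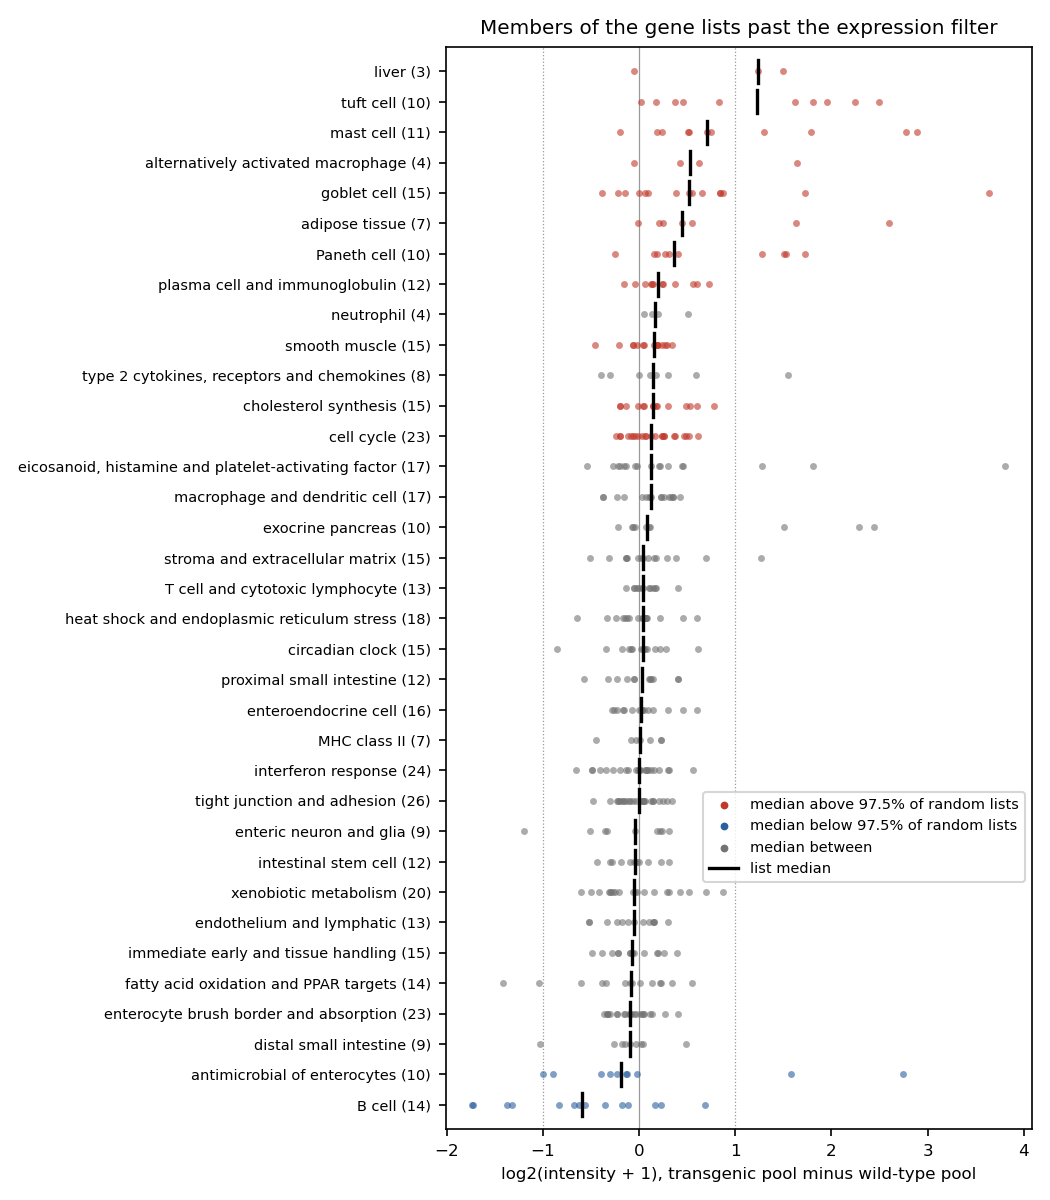
Difference of log2(intensity + 1), transgenic pool minus wild-type pool (horizontal), for each member past the expression filter (points) of the 35 gene lists with at least 3 such members, with the list median (black bar) and the number of members in brackets. Red lists stood apart from random lists on the high side and blue lists on the low side. The tuft cell and mast cell medians stand at 1.22 and 0.71, the B cell median at -0.59 and the tight junction median at -0.0023.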

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

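The tests on segment of the gut, on genes of like intensity, on pancreatic tissue and on leukocytes of every kind were chosen only after the values they use had been seen. The tests on large intestine, intensity trend, lymphoid follicles and adipose tissue were written before their own values were seen, but after the patterns they address had been seen.

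Probe sets without a single gene name were left out of the comparison by gene, and 15 of them were higher in the transgenic pool by 2-fold, above their level in the wild-type pool, and 8 were lower. Among the higher were 2 probe sets shared between gasdermin C genes, with log2 differences of 4.45 and 2.92, and 3 shared between Sprr2a genes, small proline-rich proteins of the epithelium, at 2.84, 2.21 and 1.87. Lower were a probe set shared by the fatty acid hydroxylases Cyp4a31 and Cyp4a10, at -1.41, and one shared by the alpha globin genes, at -1.05.

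Epithelial genes such as Gsdmc2, Retnlb and Ang4 were higher in the transgenic pool, and several of them are also known from the large intestine. Tissue of the large intestine in that pool would bring its abundant transcripts, but 7 genes of that tissue, 2 of them past the filter, had a median difference of 0.063, with Car1 at 0.06 and Aqp8 at -0.73. A piece from further up or down the small intestine was checked by the medians of the proximal and distal lists, which lay 0.12 apart. This does not decide it, because only 9 of 13 distal genes passed the filter, without Slc10a2, Fabp6 and Fgf15. Cubn, among these 9, was lower, so a shift along the gut remains open. Removal of a loess trend left 15 of the 15 highest named genes past 2-fold. This decides nothing, as it moved no gene past the filter by more than 0.012 on the log2 scale. Genes of like intensity to these 15 had median differences of at most 0.044 in size. The deposited values thus hold no shift with intensity as large as these differences. RMA brings such medians near 0 by construction, so this is not separate support. The transgene and other differences between these particular mice remain open and untested, because each group is 1 pool.

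Some genes on the lists of tissues that adjoin the gut were higher in the transgenic pool. These were the lipase genes Pnliprp1, Pnliprp2 and Clps and the adipose genes Adipoq and Car3. Clps is also on the Paneth cell list, and Pnliprp2 and Clps read 1682 and 2099 in the wild-type pool as well. The other 7 pancreas genes past the filter had a median of -0.048 and a highest value of 0.11, where the lipase genes were higher by at least 1.51. These 7 are the list without its 3 genes past 2-fold, so each lay under 2-fold by construction. Their median is therefore no separate test. Pancreatic tissue is argued against only by values near 0 in Cela1 (-0.05), Ctrb1 (-0.07) and Prss2 (-0.08), which were known beforehand. Zg16, also among these 7, is made by the gut as well. Adipose tissue on the transgenic samples may explain Adipoq and Car3, but 7 further adipose genes had a median of 0.17, between the 0.3 set for it and the 0.1 set against it, and some of them are also expressed by the gut. It cannot be told apart from an effect of the transgene for these genes.

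B cell genes were lower in the transgenic pool while plasma cell genes were not. Fewer leukocytes of every kind is argued against by the T cell list, whose median was 0.040. Less lymphoid follicle tissue in the piece taken could lower B cell genes, as Peyer's patches are unevenly spread along the gut. The median of 6 follicle genes not of B cells was -0.11, between the -0.3 set for this explanation and the -0.1 set against it. Of these 6, 5 lay below 0, the lowest being Mfge8 at -0.47, and Chst4 lay at 0.24. Glycam1, a gene of lymphoid vessels seen only afterwards, was 2.00-fold lower. Cxcl13 and Madcam1, outside these 6 and also picked after their values were seen, differed by -0.84 and -0.52. A difference in the tissue sampled and an effect of the transgene on B cells cannot be told apart with 1 pool each.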

How the results depend on the processing

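One alternative, lists without members that another list also holds, was chosen after seeing the data. Without replicate arrays no alternative tests the spread between mice. The counts of genes past 2-fold, 72 higher and 24 lower, ran from 50 to 75 and from 15 to 26 under the other filters, summaries, scalings and the larger pseudocount. Under the filter at the 75th percentile all 50 higher and all 15 lower genes were among those of the main setting, as were the 66 and 18 under a pseudocount of 16. The size of change moved the counts most, by construction, to 199 and 172 at 1.5-fold and to 31 and 3 at 3-fold. The number of genes past 2-fold whose probe sets all went one way was 25 and ran from 17 to 27, with no value under the mean over probe sets. The mast cell, goblet cell, Paneth cell, tuft cell, B cell and adipose lists stayed on their side of the random lists in every alternative run. The filter at the 75th percentile, which leaves fewer members, gave medians of 1.95 for tuft cell, 0.84 for Paneth cell and -0.36 for B cell genes, and 1.64 for the single remaining alternatively activated macrophage gene. Without a filter the mast cell and adipose medians were 0.52 and 0.23, and with the mean over probe sets the adipose median was 0.25. The tuft cell median was 0.64 without a filter and 0.86 with the mean over probe sets. The liver median was 0.071 without a filter, where it lay within random lists, and 0.62 with the mean over probe sets. The antimicrobial, cell cycle, plasma cell, smooth muscle and cholesterol synthesis lists each came within random lists in 1 or 2 alternatives, so their percentiles are weak. Lists within random lists also moved apart from them in some alternatives: the eicosanoid list in 3 (0.44 with the filter at the 75th percentile, but -0.02 with the mean over probe sets), the macrophage and dendritic cell list in 3, the pancreas list in 1 (0.81), the enteric neuron list in 1 (-0.39) and the brush border list in 1. Of 998 values of named genes, 962 moved by less than the SD between probe sets and the others by more. Of genes past 2-fold, 1 changed sign, Ang, to -0.59 without probe sets that can match other transcripts. Its value then came from another of its probe sets, and why these differ was not tested. Of named genes under 2-fold, 11 changed sign under at least 1 alternative, among them Ocln, Cldn2, Cxcl1 and C1qb. Ang, Mid1, Dclk1 and Apoh lost 2-fold under the mean over probe sets, and Angptl4 under that, a pseudocount of 16 and the removal of shared probe sets. Dim values limit the fold of genes such as Adipoq, which was 1.83 on the log2 scale with a pseudocount of 16, against 2.60.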

Other observations

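Further genes past 2-fold, chosen after their values were seen, fall outside the fixed lists. Higher in the transgenic pool were Capn13, a calpain (707 against 154), Cd55, a regulator of complement (1970 against 608), Car4, a membrane carbonic anhydrase (5269 against 2177), Gpx2, the epithelial glutathione peroxidase (2.43-fold higher), Klk1, tissue kallikrein (3060 against 1281), Slc13a1, a sulfate transporter (3058 against 1135), and S100g, an intestinal calcium-binding protein (452 against 151). The Klk1 value came from a probe set that can match other transcripts. Igf1, a growth factor, read 378 against 166, and Mmp10, a matrix metalloproteinase, differed by 1.02 on the log2 scale. Lower were Cxcr4, the receptor of a lymphocyte chemokine (48.2 against 103), Ces1g, a carboxylesterase (115 against 245), and Ceacam10 (186 against 413).

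Members of the gasdermin family differed in the size of their difference. Gsdmc2 differed by 4.97 on the log2 scale and the related pseudogene Gsdmcl-ps by 2.01, the latter from 25.1 in the wild-type pool. Probe sets that Gsdmcl-ps shares with related genes, both below the filter, differed by 0.37 and -0.02, and Gsdmcl2 by 0.05. The probe sets of Gsdme past the filter went in opposite directions, at -0.66 (181 against 285) and 0.22. Gsdmd, which is expressed at 2780 and 2894 in the transgenic and wild-type pools, differed by -0.06. Duoxa2 differed by 2.74, whereas its neighbour in function Duoxa1 differed by 0.22. In the resistin-like family, Retnlb differed by 3.64 and Retnla by 1.64.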
